A study of Homo sapiens with 4 samples.

How the data were processed

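Gene expression was measured in 4 cultures of human breast cancer cell lines on Agilent one-colour 60-mer arrays, 1 array per group. The groups were MDA-MB-231 cells with an empty vector, MDA-MB-231 cells labelled as overexpressing ALDH1A3, MDA-MB-468 cells with a scramble shRNA and MDA-MB-468 cells with an shRNA against ALDH1A3. All were polyclonal cells selected with puromycin, per the labels. Total RNA was extracted with TRIzol and a column kit, mixed with spike-in RNA, converted to cDNA and amplified with labelled CTP, per the labels' protocols. The 4 arrays lay on the same slide, so slide could not be compared as a batch, and position on the slide and group cannot be told apart.

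The deposited files hold each array's spot intensity on a linear scale, with the background already subtracted in the processed signal by Agilent Feature Extraction 11.0.1.1, per the file headers and the submitters' processing notes. They also hold flags for outlier spots, saturation and signal well above background, and a modelled error of each processed signal, per the file headers. No normalisation between arrays is recorded in the sources used here.

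From these, the log2 processed signal of each array was taken minus the log2 of that array's 75th percentile over non-control spots. Each array had 58717 non-control spots of 50599 probes, of which 902 were spotted 10 times. Spots flagged as non-uniform or as population outliers were left out, spots of a probe were averaged on the log2 scale, and 18 probes were lost. No non-control spot was saturated. Probes carry an accession in the files, and 28174 probes (55.7%) were named through the RefSeq gene table of assembly GRCh38.p14, giving 20496 genes. The other 22425 probes were not named. The array design was made on hg19, so the table served only for names and for which genes neighbour each other, and no coordinates are given. Of the probes of a gene, the one with the highest mean over the 4 arrays was used.

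The comparisons were 3 differences of log2 values: ALDH1A3 overexpression minus vector in MDA-MB-231, ALDH1A3 shRNA minus scramble in MDA-MB-468, and the MDA-MB-468 scramble array minus the MDA-MB-231 vector array. A gene counted as higher or lower when it differed by at least 2-fold with its probe well above background on both arrays. Where only 1 array was well above background, the difference is a bound: the bright value against the higher of the dim probe's own value and the lowest value among probes well above background on that array, written "at least N-fold". A gene whose bound was at least 2-fold counted as higher or lower too. A gene well above background on neither array counted as not measured. With 1 array per group there is no replicate check, no test was possible and no p-value is given. The number of arrays limits the precision of every value.

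Technical error was described in 3 ways. The scanner software's modelled error gave a median of 0.20 on the log2 scale for a difference between arrays. Spots of the same probe on 1 array had a median SD of 0.053 to 0.057. After scaling, 7 spike-in RNAs well above background on every array differed with an SD of 0.039 between the MDA-MB-231 arrays and 0.034 between the MDA-MB-468 arrays. None of these includes the spread between cultures.

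Before the data were examined, 22 gene lists with 612 entries were fixed, of which 603 entries were on the array under a name. For each list, the median log2 difference of its measured members is given as a percentile among 10000 random lists of the same size, matched on mean signal in 20 bins. This percentile describes these arrays and is no test of the conditions, and members of a list are co-regulated, which random lists are not. The genes named in the text were chosen by a rule fixed at the same time: ALDH1A3; per comparison within a line the 12 largest differences in each direction among called genes well above background on both arrays with a symbol and an mRNA accession; the 4 largest bounds in each direction; up to 2 members of each list in each direction; genes called in both lines, up to 12 per direction shared relative to the labelled ALDH1A3 level and up to 6 per opposite direction; and 4 in each direction between the control arrays. Names of the LOC, FLJ, KIAA and open-reading-frame kinds, XIST and Y-linked genes were left out. A few genes that the rule picks are not reported here.

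The calling was tested on simulated data, with the measured spot noise and changes planted in 50 genes per size among 20496 genes. In the simulated MDA-MB-231 comparison, changes of 3-fold and 4-fold were recovered in 100% of genes and changes of 2-fold in 58%. In the simulated MDA-MB-468 comparison these shares were 100% and 52%. A planted 2-fold change sits at the calling threshold, so noise alone decides whether it is called. The noise was that between spots of the same probe within an array, and it leaves out differences between arrays and cultures. The shares were not split by signal, so they do not show recovery in dim genes. They check the calculation and not how often true changes are found. Of 20296 genes with no planted change, 52 were called in the first simulation and 6 in the other. The list percentile was tested on 200 random lists of 30 genes from the simulated MDA-MB-231 comparison. Of these, 2% fell outside the central 95% with no shift, and 100% lay above it after a shift of 0.3 on the log2 scale. Simulated genes had independent noise, so this checks the calculation and not how often lists of co-regulated genes fall outside. On the measured arrays, 18 of the 44 list medians within a line lay under percentile 2.5 or above 97.5, where 5% of random lists do. An extreme percentile was therefore common among these lists.

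The alternatives were normexp background correction with an offset of 50 followed by quantile normalisation, quantile normalisation of the processed signal, centring on the median, spike-in scaling, only genes well above background on both arrays, no filter on dim probes, thresholds of 1.5-fold and 3-fold, the mean of all probes of a gene, and keeping outlier spots. The mean of all probes with dim values raised to the floor used for bounds was added after seeing the data. The median spot signal was used for normexp, in place of the mean signal, which the columns used here do not hold. The normexp offset of 50 is added to every signal, which by itself shrinks the log2 differences of dim probes. The tools were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.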

Results

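Expression profiles were collected from MDA-MB-231 and MDA-MB-468, 2 lines of triple-negative breast cancer, to ask which genes follow the level of ALDH1A3, an aldehyde dehydrogenase that makes retinoic acid from retinaldehyde. By the labels, ALDH1A3 was overexpressed in MDA-MB-231 and targeted by an shRNA in MDA-MB-468, each with a control culture and 1 array per group. Between 67.2% and 69.6% of non-control spots were well above background on each array, and the 75th percentile of the processed signal lay between 1045 and 1389. No group had a replicate, so each difference below compares 1 array with another and has no replicate check. The modelled technical error of a difference had a median of 0.20 on the log2 scale.

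ALDH1A3 was read by 1 probe, which matched NM_000693. Its log2 signal relative to the 75th percentile was -1.13 on the MDA-MB-231 vector array, -0.94 on the array labelled ALDH1A3 overexpression, 4.18 on the MDA-MB-468 scramble array and 2.16 on the MDA-MB-468 shRNA array. ALDH1A3 was thus 4.06-fold lower on the shRNA array than on the scramble array, beyond the modelled error. On the array labelled overexpression it was 1.14-fold higher than on the vector array, a log2 difference of 0.19 with a modelled error of 0.20. The place of the probe in the transcript is not given in the sources used here, and a probe outside the inserted cDNA checks nothing, so this value neither bears out nor contradicts the label. The control arrays of both lines differed in ALDH1A3 by 5.31 on the log2 scale, with MDA-MB-468 the higher.

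**Figure D1:**
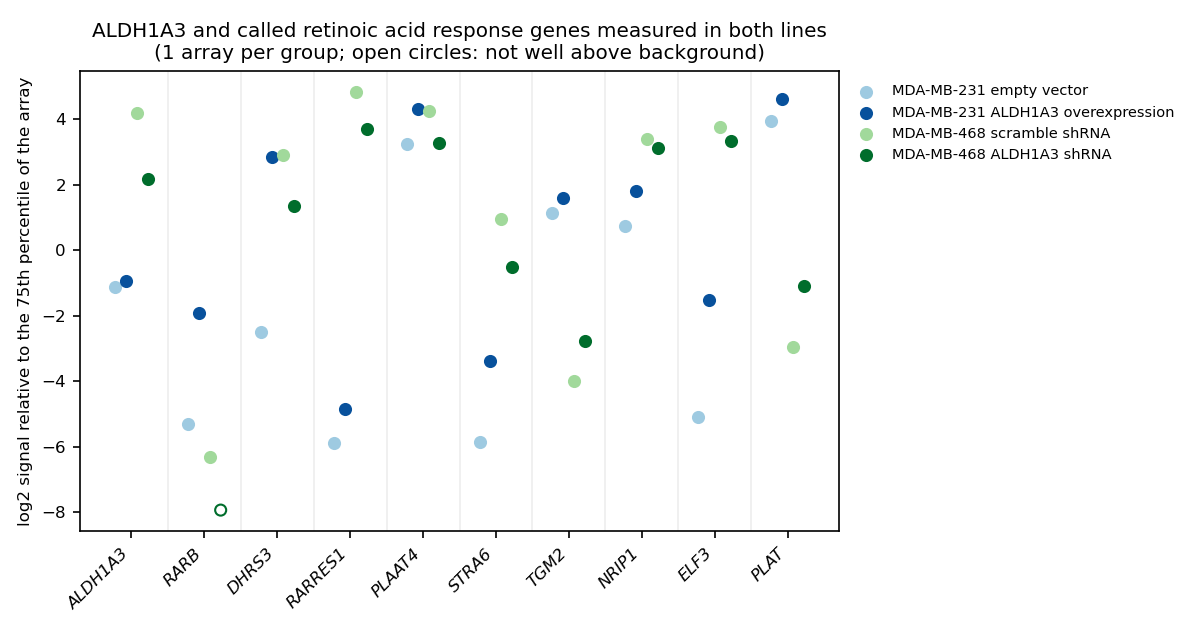
Log2 signal relative to the 75th percentile of the array (y axis) of ALDH1A3 and of the retinoic acid response genes called in either line and measured in both (x axis), with 1 point per array and open circles where the probe was not well above background. DHRS3 stood at 2.84 on the array labelled ALDH1A3 overexpression against -2.49 on the vector array, while ALDH1A3 stood at -0.94 and -1.13.

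In MDA-MB-231, 7 of the 28 measured genes of the retinoic acid response were at least 2-fold higher on the array labelled ALDH1A3 overexpression, none was 2-fold lower and 21 differed by less. DHRS3, a retinaldehyde reductase, was 40.2-fold higher than on the vector array and showed the largest difference of any named gene measured on both arrays. ELF3, an epithelial transcription factor, was 11.9-fold higher, RARB, a retinoic acid receptor, was 10.5-fold higher, and STRA6, a membrane transporter of retinol, was 5.52-fold higher. RARRES1 was 2.07-fold higher. PLAAT4 and NRIP1, chosen after their values were seen, were 2.11-fold and 2.09-fold higher. The list's median difference was 0.50 on the log2 scale, at percentile 100 of the random lists, and 0.32 with normexp and quantile normalisation, with which RARRES1 fell under 2-fold. The other probe of RARB differed by 2.43 on the log2 scale, while DHRS3, ELF3, STRA6 and RARRES1 had no other probe measured on both arrays. The list of retinoid metabolism and transport had a median of -0.02 at percentile 59.8, with none of 21 members called, and the other aldehyde dehydrogenases a median of 0.035 at percentile 80.3, with none of 15 called.

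Some inflammatory genes were also higher on that array. Of 34 measured inflammatory cytokines and NF-kB targets, 5 were higher, 1 was lower and 28 differed by less than 2-fold, with a list median of 0.42 at percentile 100. IL1B was 4.52-fold higher and IL1A at least 3.76-fold higher, both encoding interleukin-1 cytokines, and IL24 was 2.07-fold lower. The MHC class II list had a median of 0.27 at percentile 99.98, with CTSS, a lysosomal protease, 2.39-fold higher and the other 17 measured members uncalled. Interferon-stimulated genes had a median of 0.12 at percentile 99.9 and cell cycle genes 0.11 at percentile 99.99, with no member of either called. With spike-in scaling these 3 medians were 0.48, 0.32 and 0.31. IL24 fell under 2-fold with spike-in scaling and with the mean of its probes, and IL1A and CTSS with normexp and quantile normalisation. The higher inflammatory genes CXCL2, CSF3 and LCN2, named after their values were seen, also fell under 2-fold with normexp and quantile normalisation. CXCL2 did so with the mean of its probes too. Ribosomal RNA, a sign of RNA composition looked at after the data were seen, was higher on the same array, with a median of 1.24 over 3 genes, against -0.05 between the MDA-MB-468 arrays.

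Few members of the remaining lists were called in MDA-MB-231. Mesenchymal genes had a median of -0.16 at percentile 1.40, cholesterol biosynthesis genes -0.18 at percentile 0.35 and hypoxia and glycolysis genes -0.19 at percentile 0.54, with no member called, and these medians turned to 0.043, 0.022 and 0.012 with spike-in scaling. That scaling raised every MDA-MB-231 difference measured on both arrays by 0.21, so the random lists moved with these medians. FOXA1, a pioneer factor of luminal cells, was 2.93-fold higher, S100A2 was 2.21-fold lower, CST1 was 2.06-fold higher and NKG7 was 2.68-fold higher, each the only called member of its list. PDGFRB was 2.05-fold lower and KDR 2.25-fold higher. S100A2 and PDGFRB fell under 2-fold with spike-in scaling, and FOXA1, CST1, NKG7, PDGFRB and KDR with normexp and quantile normalisation. The list medians lay within the central 95% of random lists for MHC class I (0.019), epithelial (-0.015), basal-type (-0.17), luminal (-0.030), stem-cell-associated (-0.13), protease (-0.044), p53 pathway (-0.021), unfolded protein and amino acid stress (-0.065), NRF2 (-0.097), immune cell (0.0012), stromal and endothelial (-0.00030) and housekeeping genes (-0.045).

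Over all genes, 191 were higher and 183 lower on the array labelled ALDH1A3 overexpression, out of 16766 measured. Other large differences were those of CAPN3, a muscle calpain, which was 24.5-fold higher, and APOL6, 17.7-fold higher. CPED1 was 14.8-fold higher, ADAMTS12 7.82-fold, CCL4, a chemokine, 6.22-fold, ARL9 6.18-fold, C3AR1, a complement receptor, 6.18-fold, and CASP8, an initiator caspase, 5.82-fold. Lower genes were led by HCAR2, the niacin receptor, at 15.0-fold and SLC32A1, the vesicular GABA transporter, at 10.4-fold. TP53TG3C was 8.09-fold lower, SLC16A6 7.36-fold, SCARA5 7.10-fold, TSSK4 6.87-fold, KRT79 5.94-fold and SLC27A2 5.44-fold. CIMIP7, LRG1 and GARIN1B were 3.98-fold, 3.72-fold and 3.71-fold lower. Measured on 1 array only, OR7C1 was at least 50.5-fold higher, IFNA7 at least 19.4-fold, and GBA3 and SMIM9 each at least 15.5-fold, while PCDH18 was at least 47.5-fold lower, GPC5 22.2-fold, RNASE3 14.3-fold and ATP2B2 10.8-fold. Of 50 called genes with an other measured probe, the mean of such probes differed at least 2-fold the same way in 9. That mean difference was -0.27 on the log2 scale for CPED1 and 0.81 for APOL6, each over 2 probes. The split into higher and lower genes was 308 and 108 with spike-in scaling, which moved the median of all genes by 0.21 on the log2 scale, and 105 and 35 with normexp and quantile normalisation, with which TSSK4, KRT79, CIMIP7 and GARIN1B fell under 2-fold.

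In MDA-MB-468, SHH, a secreted morphogen, was 25.1-fold lower on the shRNA array than on the scramble array, EYA2, a transcriptional coactivator, 9.27-fold lower, CYP4Z1, a fatty acid hydroxylase of breast tissue, 8.69-fold lower and KRT4, a keratin of mucosal epithelia, 6.44-fold lower. RGS7, a regulator of G-protein signalling, was 12.1-fold higher, FST, the activin antagonist follistatin, 5.36-fold higher, SRGN, a proteoglycan of secretory granules, 5.35-fold higher and COL17A1, a hemidesmosome collagen, 4.17-fold higher. In all, 215 genes were higher and 257 lower out of 16946 measured, against 68 and 113 with normexp and quantile normalisation, with which COL17A1 fell under 2-fold. Of 67 called genes with an other measured probe, the mean of such probes differed at least 2-fold the same way in 31. On the log2 scale the other probes differed by -3.08 for CYP4Z1, -0.37 for HHLA1, 2.06 for TGM2, 0.30 for CXCL1, -1.41 for ELF5, -0.93 for NRAD1, 1.25 for SLC2A3 and -2.22 for AKR1C1.

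Retinoic acid response genes went both ways on the shRNA array. DHRS3 was 2.91-fold lower, STRA6 2.77-fold lower and RARRES1 2.16-fold lower. PLAT, the tissue plasminogen activator, was 3.65-fold higher and TGM2, a transglutaminase, 2.34-fold higher, under 2-fold with normexp and quantile normalisation. Of 30 measured members 4 were lower, 2 higher and 24 differed by less than 2-fold, and the list median was -0.17 at percentile 0.15. ALDH2 was 2.89-fold lower, with the other 15 measured aldehyde dehydrogenases uncalled and a list median of -0.10 at percentile 5.41. ALDH1A1, among the uncalled, differed by -0.86 on the log2 scale and its other probe by -2.62. The retinoid metabolism list had a median of -0.075 at percentile 10.1, with none of 24 called.

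Mesenchymal and inflammatory lists had the largest medians in MDA-MB-468. Of 33 measured mesenchymal genes 4 were higher and 1 lower, with a median of 0.49 at percentile 100. VIM, the intermediate filament vimentin, was 3.49-fold higher and TGFBI 2.11-fold higher, and FN1, fibronectin, was at least 2.23-fold lower. Of 28 inflammatory genes 7 were higher and none lower, with a median of 0.41 at percentile 100; CXCL1, a neutrophil chemokine, was 3.86-fold higher and IL6 3.17-fold higher. Hypoxia and glycolysis genes had a median of 0.26 at percentile 100, with ANGPTL4 2.57-fold and SLC2A3 2.36-fold higher among 3 called of 25. GDF15, a stress cytokine, was 2.58-fold higher in the p53 target list, whose median was 0.11 at percentile 98.0, and the MHC class I list had a median of 0.17 at percentile 100 with no member called. With normexp and quantile normalisation the mesenchymal median was 0.32 and the inflammatory one 0.24, and FN1 and SLC2A3 fell under 2-fold. Also under 2-fold in that setting were the higher mesenchymal genes AXL and LOX and the higher inflammatory genes IL1B, IL24, CXCL3, CXCL8 and CSF2. AXL, LOX, CXCL3, CXCL8 and CSF2 were named after their values were seen.

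Of 20 measured luminal genes 3 were lower on the shRNA array and none higher, with SPDEF 2.57-fold and MYB 2.38-fold lower and a list median of -0.26 at percentile 0.020. Epithelial genes had a median of -0.12 at percentile 0.35, and -0.072 with spike-in scaling, with ELF5 2.77-fold lower and the other 33 uncalled. AKR1C1 and AKR1C3, aldo-keto reductases, were 4.81-fold and 4.14-fold lower in the NRF2 target list, whose median was -0.13 at percentile 0.85. Cholesterol biosynthesis genes had a median of -0.16 at percentile 0 with no member called. The basal-type list went both ways, with SERPINB5 3.32-fold higher and CRYAB 2.06-fold lower and a median of 0.048. In the stem-cell-associated list HEY1 was 2.27-fold and PROCR 2.13-fold higher and NRAD1, a long non-coding RNA, 2.10-fold lower, with a median of 0.11. SERPINE2 was 2.63-fold higher and SLPI 2.26-fold lower in the protease list (median 0.066), and among interferon-stimulated genes (median -0.023) XAF1 was at least 5.42-fold and TRIM22 at least 2.79-fold lower while HERC5 was 2.30-fold higher. The medians of MHC class II (-0.13), cell cycle (0.017), unfolded protein and amino acid stress (0.054), immune cell (-0.0058), stromal and endothelial (0.17) and housekeeping genes (0.013) lay within the central 95% of random lists, with no member called. HEY1, NRAD1 and TRIM22 fell under 2-fold with normexp and quantile normalisation, and CRYAB with spike-in scaling.

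**Figure D2:**
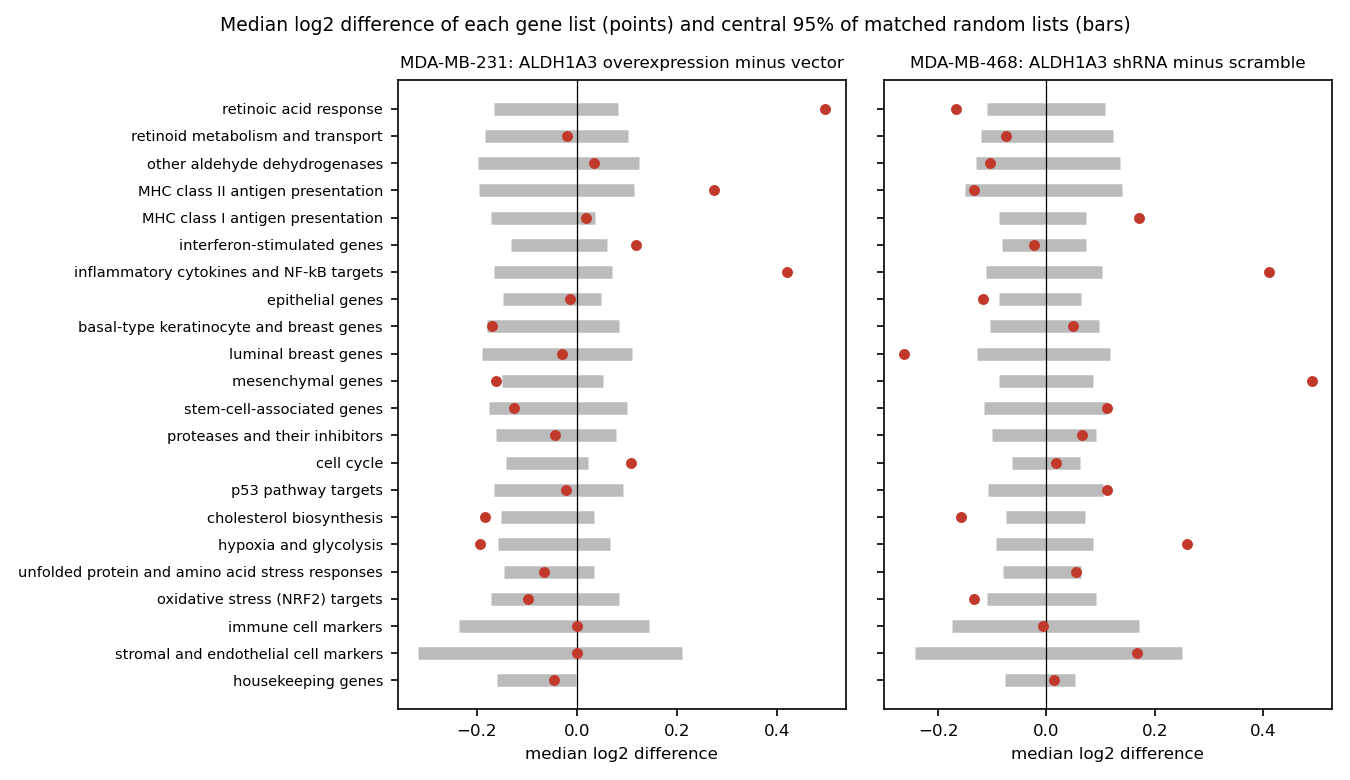
Median log2 difference (x axis) of each of 22 gene lists (y axis) between the arrays of MDA-MB-231, left, and of MDA-MB-468, right, as points, with bars for the central 95% of 10000 random lists matched on signal. The retinoic acid response list lies at 0.50 in MDA-MB-231 and at -0.17 in MDA-MB-468, and the mesenchymal list at -0.16 and 0.49. Spike-in scaling, which moves the random lists too, put the mesenchymal median in MDA-MB-231 at 0.043.

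Further genes that were higher on the shRNA array by the fixed rule were KCNIP4 (7.11-fold), ADCYAP1 (6.66-fold), VNN1 (5.78-fold), HHLA1 (5.22-fold), ROBO4 (5.19-fold), LRCOL1 (5.16-fold), KANSL1L (4.28-fold) and SLC35G2 (4.16-fold). Those lower were AJM1 (21.0-fold), PCDHGC4 (12.8-fold), ZNF431 (12.1-fold), PRR9 (11.8-fold), OR1N2 (7.69-fold), TBC1D32 (7.55-fold), OR2Z1 (6.69-fold) and CD40LG (5.63-fold). With 1 array well above background, OR2AK2 was at least 39.5-fold, H2BC1 10.3-fold, GCGR 9.11-fold and TNFSF14 9.09-fold higher, and BPIFB3 was at least 46.4-fold, PHF24 13.9-fold, THRSP 13.4-fold and INTS6L 12.1-fold lower. HHLA1 turned lower when its probes were averaged, through a probe well above background on the scramble array only, with a log2 difference of -0.90 when dim values were raised to the floor used for bounds. VNN1, LRCOL1, KANSL1L, SLC35G2, OR2Z1, CD40LG and GCGR fell under 2-fold with normexp and quantile normalisation.

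In both lines, 15 genes were called in the same direction relative to the ALDH1A3 level that the labels give, which the probe bore out only in MDA-MB-468. Higher on the array labelled overexpression and lower on the shRNA array were 8 genes, among them the retinoid genes DHRS3, STRA6 and RARRES1, and TMPRSS4, a membrane protease, SUSD4, ZSCAN4 and OR2Z1. The eighth, MIR155HG, fell outside the rule for names and was named after its values were seen. Lower on the array labelled overexpression and higher on the shRNA array were 7 genes, including HSD3B1, a steroid dehydrogenase, PGF, placental growth factor, SCG5, IL24 and LRRTM1, with VAC14-AS1 and LINC00518 named after their values were seen. These counts stood against 1.21 and 1.14 genes for independent lists over the 15933 genes measured in both lines, and against 1.64 and 2.31 within bins of mean signal. They were 2 and 1 with normexp and quantile normalisation, against 0.40 and 0.072 within bins. With spike-in scaling they were 10 and 2, against 2.66 and 1.30. At 1.5-fold, 98 genes went the way of the labels against 62.36 within bins, and 94 the opposite way against 58.41. With no filter on dim probes, 110 went the way of the labels against 111.71 within bins, and 88 the opposite way against 100.24. An excess the way of the labels was therefore not seen in every setting. At 1.5-fold the opposite way showed an excess too. In the main setting a further 7 genes went the opposite way relative to these labels, against 2.37 for independent lists, and 2 did with normexp and quantile normalisation. Of the genes named here, DHRS3, STRA6, PGF, CLMP and EDN2 stayed at least 2-fold in both lines with that setting, while PGF fell under 2-fold in MDA-MB-231 with spike-in scaling. IL1B, NOX5, CLMP and NR5A2 were higher on both the array labelled overexpression and the shRNA array, 4 genes against 1.88 within bins of signal. EDN2, CD86 and PDE9A were lower on both, 3 genes against 2.12 within bins. In MDA-MB-231 and MDA-MB-468 in turn, the other probe differed on the log2 scale by 0.025 and -0.17 for NR5A2, -0.54 and -1.15 for SUSD4, -0.58 and 0.32 for IL24, -0.48 and 0.018 for VAC14-AS1, and -0.023 and 1.00 for LINC00518. Measured in MDA-MB-468 only, that of STRA6 differed by -0.72 and that of TMPRSS4 by -1.71. Across the 15275 genes well above background on all 4 arrays, the differences in the 2 lines, overexpression minus vector and scramble minus shRNA, had a Pearson r of -0.024 and a Spearman rho of -0.040, a correlation across genes, which are not independent replicates.

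**Figure D3:**
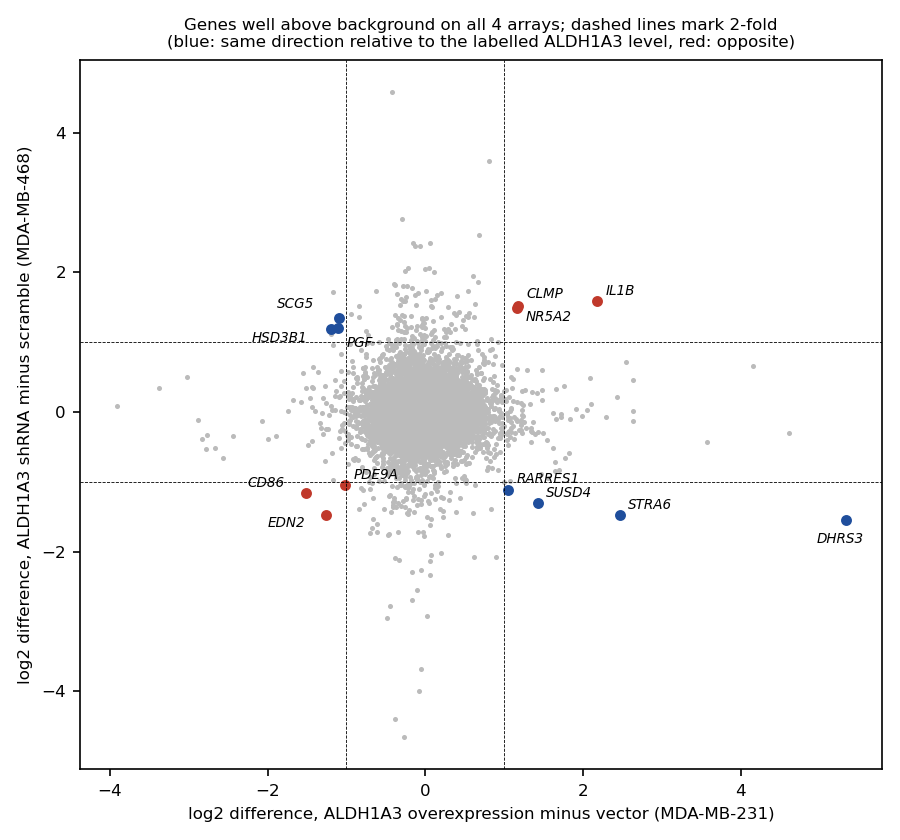
Log2 difference of each gene between the MDA-MB-231 arrays (x axis, overexpression minus vector) and between the MDA-MB-468 arrays (y axis, shRNA minus scramble), with 1 point per gene well above background on all 4 arrays and dashed lines at 2-fold. DHRS3 lies at 5.33 and -1.54, and IL1B, higher on both axes, at 2.18 and 1.59.

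The control arrays set the lines apart far more widely, with 3165 genes higher and 3285 lower in MDA-MB-468 than in MDA-MB-231 out of 17338 measured. The largest differences were those of MGP (13.50 on the log2 scale), KLK6 (11.65), S100A14 (11.29) and KLK8 (11.02) on the MDA-MB-468 side and of MMP1 (-13.04), LDHB (-12.60), GSTP1 (-11.72) and BASP1 (-10.54) on the MDA-MB-231 side. Of 34 epithelial genes 33 were higher in MDA-MB-468, with a median of 4.89 at percentile 100, and of 35 mesenchymal genes 26 were lower and 5 higher, with a median of -2.20 at percentile 0. The retinoic acid response list had 16 of 30 members higher and 5 lower, with RARRES1 at 10.71 and PLAT at -6.89, and a median of 1.16 at percentile 100. Lower in MDA-MB-468 were 12 of 18 MHC class II genes (median -2.05), 25 of 45 interferon-stimulated genes (median -1.27) and 22 of 30 inflammatory genes (median -2.29), all at percentile 0. These arrays differ in both cell line and control construct.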

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

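The tests in this part were chosen after the results were seen, except that of the brightness of other probes, and no group had enough arrays to look for outlying samples.

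Some genes moved the same way although ALDH1A3 was meant to go up in one line and down in the other, a difference between the lines that was not tested. IL1B differed by 2.18 on the log2 scale in MDA-MB-231 and by 1.59 in MDA-MB-468. NOX5 differed by 1.18 and by at least 1.34, CLMP by 1.18 and 1.52, and NR5A2 by 1.17 and 1.49. EDN2 differed by -1.26 and -1.47, CD86 by -1.52 and -1.16, and PDE9A by -1.01 and -1.04. The inflammatory list had a median of 0.42 in MDA-MB-231 and 0.41 in MDA-MB-468, and the cholesterol biosynthesis list one of -0.18 and -0.16. Spike-in scaling, which moves the random lists too, put the cholesterol biosynthesis median in MDA-MB-231 at 0.022. Probes not named by the RefSeq table also held signal: 253 of them were higher and 340 lower on the array labelled overexpression than on the vector array, and 242 were higher and 287 lower on the shRNA array than on the scramble array.

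Of 28 measured retinoic acid response genes 7 were higher and none lower on the array labelled ALDH1A3 overexpression, while the ALDH1A3 probe differed by 0.19. Carry-over of MDA-MB-468 RNA would bring that line's abundant transcripts: from the 50 genes that most set it apart, its share at the upper quartile would give the list a median of 0.00014, against 0.50 seen. The list median also lay above the central 95% of signal-matched lists by at least 0.24 under 3 normalisations, although normexp cut it to 0.32. In the main setting this repeats the comparison that gave the list its percentile. It is therefore no separate test of whether a drift of genes of like signal was the whole cause. Whether the probe reads a part of the transcript that the insert lacks cannot be told apart from a failed overexpression by the 0.19, because the place of the probe is not given. Raised ALDH1A3 activity, which the design names, stays open as a biological explanation that was not tested.

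On the MDA-MB-468 shRNA array 4 of 33 measured mesenchymal genes were higher and 1 lower, and 7 of 28 inflammatory genes higher. Of these, AXL, LOX, FN1, IL1B, IL24, CXCL3, CXCL8 and CSF2 fell under 2-fold with normexp and quantile normalisation. The 50 genes that most set MDA-MB-231 apart also differed by a median of 0.38, with an upper quartile of 0.86. They were picked partly for low values on the same scramble array, which by itself can raise these differences. Against their level in MDA-MB-231 the rise is a share of 0.040% at the upper quartile. Such carry-over of MDA-MB-231 RNA gives the mesenchymal list a median of 0.0016, against 0.49 seen, and the inflammatory list 0.0024, against 0.41. Both list medians lay above the central 95% of signal-matched lists by at least 0.15 under 3 normalisations, although normexp cut them to 0.32 and 0.24. In the main setting this repeats the comparison that gave both lists their percentile. It is therefore no separate test of whether a drift of genes of like signal was the whole cause. Loss of ALDH1A3, selection of the polyclonal cells and other targets of the shRNA may each account for the higher lists, and none was tested, since 1 shRNA and 1 array were available here.

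Many genes called in MDA-MB-231 had other probes that differed less. If those probes were too dim to show the difference, brighter ones should follow it. Of 28 genes with an other probe brighter than the median spot, 17.9% had other probes that on average followed it at least 2-fold. The exact 95% interval was 6.06% to 36.9%, and the share was 51.9% of 27 genes in MDA-MB-468. That average takes in dim probes of the same gene, so it cannot settle whether dimness hid the difference. Transcript forms read by 1 probe, or a fault of that probe, may lie behind these calls and were not told apart.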

How the results depend on the processing

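No paired analysis was possible because each group had 1 array, and no array could be left out in turn for the same reason. Leaving out saturated spots was not run, since no non-control spot was saturated. ALDH1A3 stayed lower in MDA-MB-468 under the 5 scalings, and averaging probes or keeping outlier spots could not change its single probe. Its difference in MDA-MB-231 was 0.40 with spike-in scaling against 0.19. The retinoic acid response median in MDA-MB-231, 0.50, was 0.32 with normexp, 0.70 with spike-in scaling and 0.36 with the mean of all probes, also with dim values raised. Median centring and keeping outlier spots moved no named gene by more than the modelled error, and normexp with quantile normalisation moved results most often. Some alternatives cannot move most values: a changed filter leaves genes measured on both arrays as they were, and averaging leaves genes with a single probe. The share of values that stayed, pooled over all alternatives, is therefore partly fixed in advance. Of 1178 values of 134 called named genes under all these alternatives together, 1019 moved by less than the modelled error, 551 of them not at all, 157 moved by more, and 2 reversed, both of HHLA1 in MDA-MB-468. It stood at -1.63 with the mean of all probes, where a probe well above background on 1 array only enters with its dim value, and at -0.90, under 2-fold, with dim values raised to the floor, an alternative chosen after seeing the data that left 4 genes lower in both lines with more ALDH1A3 by the labels. Spike-in scaling turned the MDA-MB-231 medians of the mesenchymal list to 0.043, of cholesterol biosynthesis to 0.022 and of hypoxia and glycolysis to 0.012. The random lists move with these medians, since the same amount is added to every difference measured on both arrays. Counts are given in the order higher and lower in MDA-MB-231, higher and lower in MDA-MB-468, higher and lower in both lines with more ALDH1A3 by the labels, and opposite between the lines. They were 191, 183, 215, 257, 8, 7 and 7 in the main setting. With normexp and quantile normalisation they were 105, 35, 68, 113, 2, 1 and 2. The offset of 50 in that setting by itself shrinks the log2 differences of dim probes. How much of the fall in counts it accounts for was not tested. With no filter on dim probes, which adds genes not measured above, they were 420, 679, 698, 519, 32, 78 and 88. Of these, 32, 78 and 88 stood against 30.93, 80.79 and 100.24 within bins of mean signal. At 1.5-fold the counts were 606, 757, 708, 713, 47, 51 and 94, and at 3-fold 79, 55, 66, 94, 1, 0 and 1. The 47, 51 and 94 at 1.5-fold stood against 21.14, 41.21 and 58.41 within bins. Spike-in scaling raised every MDA-MB-231 difference measured on both arrays by the same 0.21, and with that shift the split there was 308 and 108. It gave 2 genes lower in both lines with more ALDH1A3 by the labels. Why the spike-ins differed between the arrays was not tested. With only genes well above background on both arrays, which leaves fewer genes, 101 were lower in MDA-MB-231 and 4 higher in both lines with more ALDH1A3 by the labels. Between the control arrays 6450 genes were called, against 9777 at 1.5-fold and 3991 at 3-fold. Signal over background limits the dim genes: spots of repeated probes under a signal of 50 had a median SD of 0.19 to 0.21, against 0.046 to 0.048 above 1000.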

Other observations

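All tests and gene classes in this part were chosen after the results were seen. The median log2 difference of histone genes was 0.19 over 65 measured genes in MDA-MB-231, with none called, and -0.32 over 70 genes in MDA-MB-468, where H2BC1 was the only one called, at least 10.3-fold higher and so against the median. These medians lay at percentiles 100 and 0 of signal-matched random lists, and their signs held under all 5 scalings. Small nuclear and nucleolar RNAs had medians of 0.10 and 0.17 over 247 genes, both at percentile 100, with 6 higher and 5 lower in MDA-MB-231 and 3 higher and none lower in MDA-MB-468. Sizes depended on the scaling. With spike-in scaling the MDA-MB-231 medians were 0.40 for histone genes and 0.31 for these small RNAs. With normexp and quantile normalisation the small RNA median in MDA-MB-468 was 0.098.

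In MDA-MB-468, 27 adjacent pairs of genes on the genome were called the same way, against a mean of 7.53 and a central 95% of 3 to 13 in 10000 shuffles within bins of signal. In MDA-MB-231 there were 9 against a mean of 5.17 and a central 95% of 1 to 10, and the difference between the lines was not tested. Among the MDA-MB-468 pairs were neighbours of the AKR1C, S100A7, CYP4 and POU2AF families and the pairs ELF5 and EHF and EREG and AREG, all named after their values were seen. Related neighbours can share a probe's signal, so pairs with like names were left out to test the hypothesis that neighbouring genes change together. This filter went by name only, so ELF5 and EHF, and EREG and AREG, stayed in, and likeness of sequence was not checked. The remaining 11 pairs reached but did not exceed the upper end of the central 95% of shuffles, which was 11 with a mean of 5.98. In MDA-MB-231 there were 4 such pairs against a mean of 4.06, so the hypothesis gained no backing there.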
